A study of Homo sapiens with 21 samples.

How the data were processed

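RNA sequencing was measured in NCI-H1048 cells, an established human small cell lung cancer line, and in tumours of a patient-derived small cell lung cancer xenograft grown in immunodeficient mice. The labels describe a non-stranded library kit with paired-end sequencing. The authors deposited a table of raw read counts per gene and a table of FPKM values per gene, both with all 21 libraries as columns, and both hold 58735 genes. Alignment with STAR and use of DESeq2 are named in the submitters' processing notes, without versions. The counting tool and the annotation release are not given in the sources used here. The labels' protocol text names a mouse build for the alignment, whereas the submitters' processing notes name hg38 and GRCh38. All 58735 gene identifiers were found in GENCODE release 29 for GRCh38, with identical start and end positions, so coordinates are given on GRCh38. How reads of the mouse host were treated in the xenograft libraries is not given in the sources used here.

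The deposited counts are whole numbers that sum to between 11651893 and 18387442 per library, and were used as deposited. A floor of 3 counts stands for a group at 0, and it covers counting error only, since no molecular identifiers are described. In the FPKM values that the authors deposited, the count of each gene was divided by gene length and by 1 constant per library, whose ratio to the library total lay between 0.934 and 1.08. FPKM values were used only in an alternative. No column of the tables belonged to another sample. Because the kit does not mark strand, reads of overlapping antisense genes cannot be told apart.

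Each comparison was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, genes kept by filterByExpr on the groups, and Benjamini-Hochberg adjustment at 0.05 over all genes tested. The 10 NCI-H1048 libraries entered 1 fit of 5 groups and the 11 xenograft libraries another. The difference between the CIRc-014 effects in xenograft and cells was tested as an interaction over 15 libraries. Fold changes are given as log2 values with a standard error, which is the fold change divided by the square root of F, and 95% intervals. CPM values were scaled with TMM factors, and values after ± are standard errors for fold changes and standard deviations for CPM.

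Lists of genes were fixed before the data were examined: G1/S E2F target, G2/M and mitosis, replication-dependent histone, p53 target, BCL2 family, homologous recombination and Fanconi, NF-kB target and inflammatory, interferon-stimulated, immediate early, ATF4 stress response, unfolded protein response, heat shock, cholesterol synthesis, hypoxia and glycolysis, ribosome biogenesis and MYC target, cytosolic ribosomal protein, mitochondrially encoded, and cyclin, CDK, RB and E2F family genes, and markers of neuroendocrine and tuft cell-like small cell lung cancer, fibroblasts, endothelium, macrophages, lymphocytes, muscle and adipocytes, red blood cells and keratinocytes. Each was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, again with an estimated correlation, and with fry. Members were counted over all genes tested and adjusted over the list alone. In the xenograft, the mean log2 CPM of each list was also compared between groups by an exact two-sided permutation test over all 462 splits.

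Named genes followed a rule fixed before the data were examined: the 8 largest rises and 8 largest falls per comparison among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 CPM and groups that did not overlap, a fixed panel of cell cycle, apoptosis and stress genes, and up to 4 members per list with the smallest adjusted p, plus the 2 members with the highest CPM that did not pass. Exceptions are stated where they occur, and some genes that the rule names are not reported.

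Alternatives planned before the data were examined were DESeq2 1.42.0, RLE factors, library totals alone, no filter, a filter of at least 1 CPM, limma on log2(FPKM + 1), leaving out each library in turn, a replicate block or a fit of only the compared groups for the cells, and, for the xenograft, 1 surrogate variable from sva 3.50.0 and limma voom with sample weights. A fit of 9 NCI-H1048 libraries without the second CIRc-005 library, and limma voom with sample weights in the cells, were added after seeing the data.

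Counts were tested on simulated data drawn with the means, library sizes and dispersions of the real libraries. The 200 changed genes were drawn from those with a mean of at least 5 CPM, so the shares do not cover weaker genes. Each gene had 1 dispersion for all libraries of a fit. With 10 libraries it included the spread of the second CIRc-005 library, also for simulated DMSO and CIRc-004 libraries. For CIRc-004 against DMSO with 10 libraries and 15676 genes, 76.1% of genes changed 2-fold and 17.9% of those changed 1.5-fold were recovered. With 9 libraries and 16279 genes the shares were 98.5% and 85.1%. For the xenograft comparison with 16212 genes they were 76.1% and 32.8%. The simulated comparisons also called 6, 15 and 7 unchanged genes, in the order given. All replicate pairs differed by more than sampling noise, with a chi-square per gene of at least 3.62. The labels describe the cell libraries as biological replicates and the tumours as coming from separate mice.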

Results

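Gene expression was measured by RNA sequencing after treatment with inhibitors of the RxL interaction of cyclins A and B, a docking contact through which these cyclins bind substrates and regulators. NCI-H1048 cells were treated for 24 h with DMSO, with 200 nM of the active inhibitors CIRc-004 or CIRc-014, with 200 nM of CIRc-005, the inactive enantiomer, or with 500 nM of PF-07104091, a CDK2 inhibitor, with 2 libraries in each group. Mice bearing a small cell lung cancer xenograft received 100 mg/kg of CIRc-014 3 times a day for 4 days (6 tumours) or vehicle (5 tumours), and tumours were taken 8 h after the morning dose. Library totals ranged from 11998239 to 18387442 counts in the cells and from 11651893 to 16139943 in the xenograft. The second CIRc-005 library stood apart, with a Pearson correlation of log2 CPM of 0.947 to its own replicate against 0.994 between the DMSO libraries. In it, the shortest of 10 equal groups of genes by length had a median deviation of 0.56 log2 units from the mean of the other libraries and the longest group one of -0.49. It entered the shared estimate of spread, and the common dispersion of the cell fit was 0.0202 with it and 0.00518 without it.

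**Figure D1:**
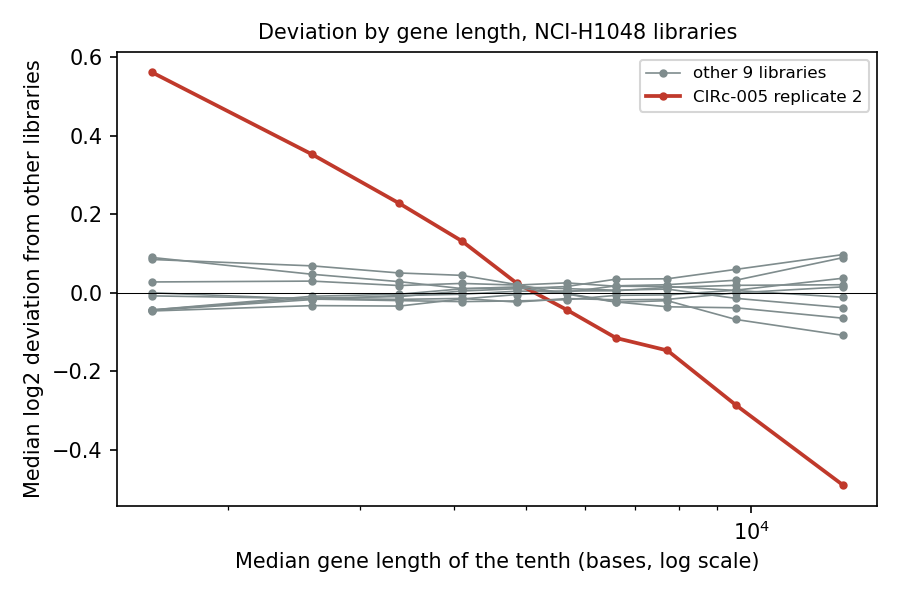
Median log2 deviation of each NCI-H1048 library from the mean of the others (y axis) for 10 equal groups of genes by length in bases (x axis, log scale), 1 line per library. The second CIRc-005 library was left out of every mean. The second CIRc-005 library runs from 0.56 for the shortest group to -0.49 for the longest.

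The first comparison asked what the active inhibitor CIRc-004 changed against its solvent. Genes of mitosis rose: CCNB1 (ENSG00000134057), encoding cyclin B1, went from 324 ± 3.79 to 906 ± 54.9 CPM (SD, n = 2 each), a log2 fold change of 1.48 ± 0.12 (edgeR adjusted p = 0.000839). AURKA and PLK1, which encode mitotic kinases, rose by 1.46 ± 0.10 and 1.34 ± 0.12, and CDC20, an activator of the anaphase-promoting complex, by 1.33 ± 0.11. Genes of the G1/S transition fell: E2F1 (ENSG00000101412), a transcription factor of S-phase entry, went from 58.2 ± 1.87 to 23.5 ± 3.16 CPM (log2 fold change -1.31 ± 0.16, edgeR adjusted p = 0.00396). The replicative helicase genes MCM6, MCM5 and MCM2 had log2 fold changes of -1.30 ± 0.12, -1.13 ± 0.14 and -0.98 ± 0.13, and CCNE1, encoding cyclin E1, of -0.82 ± 0.12.

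Of the 59 measured G2/M and mitosis genes, 37 rose with CIRc-004, none fell and 22 did not pass, and 55 rose when adjusted over the list alone. Their median log2 fold change was 0.85 (camera adjusted p = 1.46e-94, and adjusted p = 0.000937 with an estimated correlation). MKI67 (1.08 ± 0.41) and CENPF (0.62 ± 0.24) were abundant members that did not pass. MKI67 was at 613 ± 76.7 CPM with DMSO and 1294 ± 7.58 with CIRc-004. With CIRc-005, whose libraries entered the shared estimate of spread, it was at 463 ± 347 CPM. Of the 48 G1/S E2F target genes, 17 fell, none rose and 31 did not pass, and 34 fell when adjusted over the list alone, with a median of -0.53 (camera adjusted p = 2.5e-38, and adjusted p = 0.000405 with an estimated correlation). In the fit of 9 libraries, without the second CIRc-005 library, 55 of the G2/M genes rose and 39 of the G1/S genes fell (56 and 41 when adjusted over the list alone). CDC6, a replication licensing factor, was at -1.01 ± 0.11, and MCM3 at -0.99 ± 0.10, whereas RRM1 (-0.10 ± 0.11) and MYBL2 (-0.28 ± 0.11) did not pass. Outside these lists, PIF1, encoding a DNA helicase, rose by 1.96 ± 0.19, and the rises of TROAP and KNSTRN, which encode spindle-associated proteins, were 1.74 ± 0.12 and 1.57 ± 0.14. CCNA1, encoding cyclin A1, rose by 1.84 ± 0.22, and YPEL4 had the largest rise under the naming rule (2.54 ± 0.47). The falls of CDCA7, HELLS, a chromatin remodeller, and MYC were -1.23 ± 0.11, -1.14 ± 0.15 and -0.67 ± 0.11.

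Over all 16047 genes tested with CIRc-004, 176 were higher and 87 lower. Without the second CIRc-005 library, 1075 were higher and 1143 lower among 16961 genes, and all 263 genes of the fit with 10 libraries were among them. Leaving out 1 library of the compared groups left 13 genes without either DMSO library, and 23 and 15 without the first or the second CIRc-004 library.

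CIRc-014, the orally available active inhibitor, moved the same lists. AURKA, at chromosome 20 from 56369389 to 56392337 (GRCh38), went from 106 ± 3.57 to 368 ± 7.14 CPM (log2 fold change 1.79 ± 0.10, edgeR adjusted p = 0.00017, n = 2 each). CCNB1, at chromosome 5 from 69167010 to 69178245, rose by 1.52 ± 0.12, PLK1 by 1.47 ± 0.12 and CCNA2, encoding cyclin A2, by 1.03 ± 0.12. E2F1, at chromosome 20 from 33675683 to 33686404, went from 58.2 ± 1.87 to 17.9 ± 1.89 CPM (-1.70 ± 0.16), and MCM6, at chromosome 2 from 135839626 to 135876426, to 60.3 ± 4.46 from 189 ± 3.47 CPM (-1.65 ± 0.13). MCM5, UNG and CCNE2 had log2 fold changes of -1.60 ± 0.14, -1.42 ± 0.11 and -1.23 ± 0.12.

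Of the 59 G2/M and mitosis genes, 45 rose with CIRc-014, none fell and 14 did not pass, and 54 rose when adjusted over the list alone (median 0.97, camera adjusted p = 6.69e-96, and adjusted p = 0.000795 with an estimated correlation). Of the 48 G1/S E2F target genes, 18 fell, none rose and 30 did not pass, and 30 fell when adjusted over the list alone (median -0.48, camera adjusted p = 4.66e-33, and adjusted p = 0.000587 with an estimated correlation). With 9 libraries, 56 of the G2/M genes rose and 35 of the G1/S genes fell, and when adjusted over the list alone 56 of the G2/M genes rose, and 36 of the G1/S genes fell and 1 rose. Of the panel, the fall of CDKN1A, encoding the CDK inhibitor p21, was -0.55 ± 0.13. Those of MYC and CCND1, encoding cyclin D1, were -0.88 ± 0.11 and -0.74 ± 0.17. CDK1 (0.07 ± 0.28, and -0.01 with library totals), CDK2 (-0.14 ± 0.11) and MCL1 (-0.08 ± 0.10) did not pass. BCL2L11 went from 52.4 ± 1.10 to 35.4 ± 0.334 CPM (-0.57 ± 0.15) and did not pass either (edgeR adjusted p = 0.0695). Its level was 52.0 ± 11.5 CPM with CIRc-005, whose libraries entered the shared estimate of spread. STAT6, encoding a cytokine-responsive transcription factor, rose by 1.95 ± 0.26, TNFAIP8L1 by 1.77 ± 0.12 and PIMREG by 1.73 ± 0.20.

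Over all 16047 genes, 300 were higher and 249 lower with CIRc-014, and scaling by library totals alone gave 262 higher and 398 lower. Without the second CIRc-005 library, 1528 were higher and 1602 lower, and all 549 genes of the fit with 10 libraries were among them. Leaving out 1 library of the compared groups left 79 and 85 genes without the first or the second DMSO library, and 107 and 109 without the first or the second CIRc-014 library.

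The active inhibitors were compared with each other at the same dose and time. CCNB1 differed by 0.04 (95% interval -0.22 to 0.29, CIRc-014 minus CIRc-004, and -0.02 without the first CIRc-004 library), PLK1 by 0.13 (-0.13 to 0.39) and E2F1 by -0.39 (-0.76 to -0.02). No gene passed in edgeR, DESeq2 or limma on log2(FPKM + 1), with 300, 185 and 414 genes under an unadjusted p of 0.05, and 1 passed in limma voom with sample weights. Among the 563 genes called with either inhibitor against DMSO, the median difference was 0.03 and the 95% interval lay within 2-fold for 489. The difference is signed and these genes include rises and falls, so its median cannot show equal strength. The G2/M list differed by a median of 0.08 (camera adjusted p = 1.78e-06, and adjusted p = 0.342 with an estimated correlation), the histone list by -0.42 (camera adjusted p = 9.1e-08, and adjusted p = 0.359 with an estimated correlation) and the cholesterol synthesis list by 0.14 (camera adjusted p = 0.000189, and adjusted p = 0.304 with an estimated correlation). Without the second CIRc-005 library 2 genes passed, in a fit of only these groups 16 passed, and with no filter on low counts 15 passed.

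CIRc-005, named as the inactive enantiomer in the labels, was compared with DMSO. In the fit of 9 libraries, with the first CIRc-005 library alone in its group, CCNB1 was at 0.04 ± 0.09 and E2F1 at -0.04 ± 0.13. E2F1 was at 0.16 with both libraries and at 0.329 without the first (edgeR adjusted p = 0.712 and 0.0419). In the fit of 10 libraries none of the 59 G2/M or 48 G1/S genes passed (medians 0.10 and 0.04, camera adjusted p = 0.344 and 0.663). No gene passed in edgeR, with 866 under an unadjusted p of 0.05, none in limma voom or in limma on log2(FPKM + 1), with 307 and 766, whereas 1 passed in DESeq2 and, with no filter on low counts, 211 were higher and 65 lower in edgeR. The 40 cytosolic ribosomal protein genes had a median of 0.43 (camera adjusted p = 5.09e-14, and adjusted p = 0.578 with an estimated correlation), with deviations of 0.78 in the second library and -0.01 in the first. The 10 measured endothelial markers had a median log2 fold change of 2.37 (camera adjusted p = 6.42e-11, and adjusted p = 0.144 with an estimated correlation), with none passing over all genes and 5 higher when adjusted over the list alone. Over 9 libraries 1 of them passed, and 6 when adjusted over the list alone. PECAM1, an endothelial adhesion gene, had 96 and 35 counts against at most 12 in any library of the other groups, and CDH5 had 56 and 20 against at most 4. EGFL7, with 452 and 586 counts, and ESAM, with 55 and 32, lay within the 306 to 609 and the 23 to 104 of the other groups. Without the second library 5 genes passed, and without the first 5716 passed.

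The active inhibitors were then compared with CIRc-005 at the same dose and time. With CIRc-004, MCM6 was at -1.44 ± 0.13, E2F1 at -1.47 ± 0.16 and TROAP at 1.68 ± 0.12 (edgeR adjusted p = 0.000976, 0.00237 and 0.000976). Of the 59 G2/M genes 35 rose and of the 48 G1/S genes 19 fell, with medians of 0.75 and -0.52, and when adjusted over the list alone 50 rose and 34 fell (camera adjusted p = 1.36e-59 and 1.19e-30, and adjusted p = 0.00315 and 0.00071 with an estimated correlation). With CIRc-014, 41 and 20 did so, with medians of 0.88 and -0.50, and when adjusted over the list alone 52 and 29 (camera adjusted p = 7.77e-71 and 2.81e-30, and adjusted p = 0.00187 and 0.000732 with an estimated correlation). With CIRc-004 52 of the G2/M genes rose and 31 of the G1/S genes fell in the fit of 9 libraries (54 and 37 when adjusted over the list alone), and with CIRc-014 53 and 31 (56 and 33 when adjusted over the list alone). Over all genes, 276 were higher and 161 lower with CIRc-004, and 417 and 357 with CIRc-014. In fits of only the groups compared no gene passed in either comparison, with 1464 and 1718 genes under an unadjusted p of 0.05 in edgeR and 763 and 1022 passing in DESeq2 with all groups, and without the second CIRc-005 library 1494 and 2353 passed. Without the first CIRc-005 library 6469 and 6301 passed, without the first or the second CIRc-004 library 48 and 24, and without the first or the second CIRc-014 library 116 and 128.

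**Figure D2:**
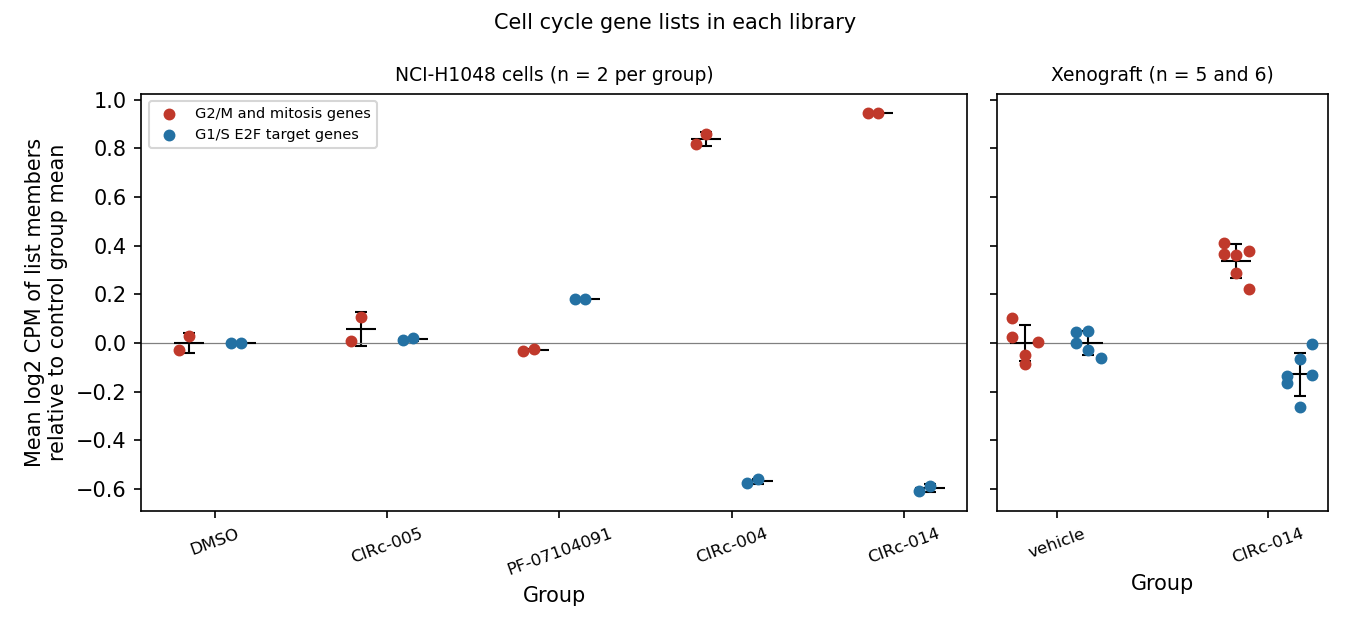
Mean log2 CPM of the G2/M and mitosis genes (red) and the G1/S E2F target genes (blue) in each library, relative to the mean of the DMSO or vehicle libraries (y axis), by group (x axis), with group mean and SD as black lines. G2/M values are 0.84 and 0.95 on average with CIRc-004 and CIRc-014 in the cells and 0.34 with CIRc-014 in the xenograft.

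PF-07104091 inhibits CDK2, the kinase partner of cyclins E and A. H1F0 (ENSG00000189060, chromosome 22 from 37805093 to 37807436), encoding the linker histone H1.0, went from 312 ± 18.4 to 122 ± 4.5 CPM (log2 fold change -1.35 ± 0.11, edgeR adjusted p = 0.00396, n = 2 each), and it was the 1 gene that passed, with 1024 genes under an unadjusted p of 0.05, 10 passing in DESeq2 and 37 with no filter on low counts. The G1/S E2F target genes had a median of 0.17 (camera adjusted p = 3.73e-07, and adjusted p = 0.0233 with an estimated correlation), with none passing over all genes and 6 higher when adjusted over the list alone. The G2/M and mitosis genes had a median of -0.06 (camera adjusted p = 0.262). Without the second CIRc-005 library, 261 genes were higher and 189 lower, and CCNE1 and CDC6 rose by 0.51 ± 0.09 and 0.47 ± 0.08 (edgeR adjusted p = 0.00374 and 0.00265). In that fit 10 of the 48 G1/S genes rose (21 when adjusted over the list alone), CDKN1A rose by 0.41 ± 0.10, and APOLD1 and SCUBE2 had the largest rises under the naming rule (1.23 ± 0.21 and 1.14 ± 0.17). No gene passed when any of the DMSO or PF-07104091 libraries was left out, each with 543 to 688 genes under an unadjusted p of 0.05 in edgeR.

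CIRc-004 at 200 nM and PF-07104091 at 500 nM were compared directly, at doses that differ. CDC6 was 153 ± 7.02 CPM with PF-07104091 and 54.8 ± 2.97 with CIRc-004 (log2 fold change -1.48 ± 0.11, edgeR adjusted p = 0.000546, n = 2 each), and the log2 fold changes of CCNE2 and E2F1 were -1.45 ± 0.12 and -1.57 ± 0.16. CDC20 and PLK1 were higher with CIRc-004 by 1.58 ± 0.11 and 1.56 ± 0.12. Of the 59 G2/M genes 42 were higher (53 when adjusted over the list alone) and of the 48 G1/S genes 29 were lower (40 when adjusted over the list alone), with medians of 0.87 and -0.76 (camera adjusted p = 8.94e-80 and 7.16e-50, and adjusted p = 0.00149 and 0.000209 with an estimated correlation). The meiotic cohesin gene REC8 was at -1.48 ± 0.13. The fit of 9 libraries had 55 of the G2/M genes higher and 42 of the G1/S genes lower (56 and 44 when adjusted over the list alone). Over all genes 263 were higher and 365 lower with CIRc-004, and 1712 and 1866 without the second CIRc-005 library. Without the first or the second CIRc-004 library 91 and 38 passed, and without the first or the second PF-07104091 library 55 and 85.

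Effects measured on separate libraries were compared across genes, which are not independent replicates. CIRc-004 against CIRc-005 and CIRc-014 against DMSO had a Pearson correlation of 0.476 and a Spearman correlation of 0.409 over 16047 genes, and shared 174 higher and 89 lower genes against 5.16 and 2.50 for independent lists. Of the 437 genes called with CIRc-004 against CIRc-005, 435 had the same sign with CIRc-014 against DMSO. These comparisons shared, in the fit of 9 libraries, 561 higher and 634 lower genes against 63.1 and 75.0 for independent lists, and 1472 of 1494 genes had the same sign. CIRc-004 against CIRc-005 and PF-07104091 against DMSO had correlations of 0.02 (Pearson) and -0.04 (Spearman), and 202 of the 437 genes had the same sign, as did 769 of 1494 without the second CIRc-005 library.

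In the xenograft, the comparison asked which genes CIRc-014 changed in tumours. CCNB1 was 92.3 ± 6.46 CPM with vehicle (n = 5) and 151 ± 7.47 with CIRc-014 (n = 6), a log2 fold change of 0.71 ± 0.09 (edgeR adjusted p = 0.00495). AURKA rose by 0.72 ± 0.09, TROAP by 0.75 ± 0.12 and TNFAIP8L1 by 0.91 ± 0.11. The fifth gene that passed, NPR3 (ENSG00000113389), encoding a natriuretic peptide receptor, rose by 3.01 ± 0.37. It lies outside the naming rule, as its mean was under the minimum of 5 CPM even in the treated tumours. NPR3 was chosen after its values were seen, and its fold change rests on low counts. No gene fell in edgeR, with 1101 genes under an unadjusted p of 0.05 in either direction, and 1 fell in DESeq2. PLK1 was at 0.75 ± 0.13, CCNA2 at 0.42 ± 0.08 and PCNA, encoding the replication clamp, at -0.43 ± 0.12, and none of them passed (edgeR adjusted p = 0.0771, 0.108 and 0.461).

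Of the 59 G2/M and mitosis genes, 2 rose in the xenograft over all genes and 32 when adjusted over the list alone, with a median of 0.37 (camera adjusted p = 7.12e-48, and adjusted p = 0.000669 with an estimated correlation). Their mean log2 CPM was 0.34 higher in treated tumours, with all 6 above every vehicle tumour (exact permutation p = 0.00216, the smallest that 462 splits can give, and 0.0497 adjusted over 23 lists). The 48 G1/S E2F target genes had a median of -0.15, with none passing over all genes and 3 lower when adjusted over the list alone (camera adjusted p = 1.62e-06, and adjusted p = 0.0903 with an estimated correlation). The 25 immediate early genes had a median of 0.41, with none passing over all genes and 11 higher when adjusted over the list alone (camera adjusted p = 3.07e-13, and adjusted p = 0.0708 with an estimated correlation). Among these 11 were JUNB (0.60 ± 0.13) and FOS (1.11 ± 0.33), which encode AP-1 transcription factors. The share of counts from mitochondrial genes ranged from 3.74% to 9.79% across tumours, and the mitochondrially encoded genes had a median of 0.29 (camera adjusted p = 4.36e-05, and adjusted p = 0.543 with an estimated correlation). The exact permutation p was 0.00649 for the score of the cyclin, CDK, RB and E2F family genes (0.0746 when adjusted over 23 lists, with 5 of 6 treated tumours above every vehicle tumour), and 0.013, 0.0195 and 0.0216 for the immediate early, G1/S and heat shock scores (0.0994 each when adjusted). DESeq2 called 32 genes higher and 1 lower, limma voom with sample weights called 16 higher, and limma on log2(FPKM + 1) called 3 higher.

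The CIRc-014 effects in xenograft and cells were tested against each other, with dose, schedule and system differing between them. The difference passed for 45 genes, of which 43 had the larger effect in the cells. Of these 45 genes, 24 had effects of opposite sign in xenograft and cells. Among them only NPR3 passed in the xenograft itself. Some of the xenograft effects lay near 0, such as those of ESPL1 (-0.006), SCAMP5 (0.006) and STAT6 (-0.01), so the sign alone does not show a reversal. In DESeq2 the difference passed for 227 genes, 122 higher and 105 lower. E2F1 differed by 1.52 ± 0.16 and CDCA7 by 1.84 ± 0.18 (edgeR adjusted p = 0.000282 for each), with cell effects of -1.73 and -1.67 and xenograft effects of -0.21 and 0.17. NPR3 differed by 3.33 ± 0.40 (edgeR adjusted p = 0.00164), with a cell effect of -0.32. Its xenograft effect rests on low counts, with a mean under 5 CPM in the treated tumours. The G2/M list differed by a median of -0.63, with 4 of 59 genes lower over all genes and 40 when adjusted over the list alone, and the G1/S list by 0.52, with 5 of 48 higher and 20 when adjusted over the list alone (camera adjusted p = 6.35e-39 and 2.73e-22, and adjusted p = 0.000557 and 0.00424 with an estimated correlation). Across 14057 genes the effects had a Pearson correlation of 0.09 and a Spearman correlation of 0.03, and of the 499 genes called in the cells and measured in both, 361 (72.3%) had the same sign in the xenograft. Of the genes called without the second CIRc-005 library, 1578 of 2894 (54.5%) had the same sign. Leaving out either DMSO or either CIRc-014 cell library left 2 to 4 genes, leaving out vehicle tumour 1 or 3 left 18 and 23, and leaving out treated tumour 1, 3, 5 or 6 left 18, 19, 16 and 20, numbered in the order of the samples.

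**Figure D3:**
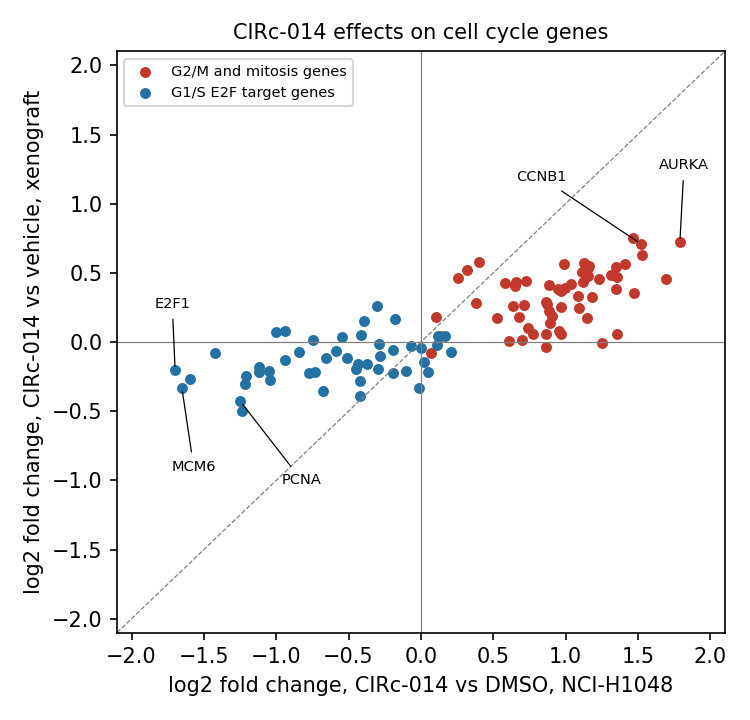
Log2 fold change with CIRc-014 in NCI-H1048 (x axis) and in the xenograft (y axis) for each measured G2/M and mitosis gene (red) and G1/S E2F target gene (blue), with equal effects on the dashed line. CCNB1 lies at 1.52 and 0.71, and E2F1 at -1.70 and -0.20.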

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

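The tests of gene length, of GC content and of the first CIRc-005 library were chosen after the result was seen. In 56 groups of xenograft values for lists and called genes, no tumour lay far enough from the others to be singled out, where chance would single out about 1 in 20.

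The CIRc-014 effect differed between xenograft and cells for 45 genes by the interaction test. The median difference, xenograft minus cells, was -0.63 for the G2/M and mitosis genes, 0.52 for the G1/S E2F target genes and 0.996 for the replication-dependent histone genes (camera adjusted p = 3.12e-07 for the last, and adjusted p = 0.029 with an estimated correlation). In the xenograft itself, 3 of 100 drawn splits of the 11 tumours, the real one included, called 5 genes or more. This share is under 0.05, but the share over all 462 splits was not determined, so chance was not excluded. The highest other splits called 153 and 36 genes, more than the real count, and whether a structure of the tumours gave these was not tested. The model with 1 surrogate variable called 5 genes.

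The second CIRc-005 library departed from all other NCI-H1048 libraries. Its deviation fell with gene length across 11656 genes (Spearman rho = -0.549). The other 9 libraries, each set against a mean without the second CIRc-005 library, lay between -0.221 and 0.202. The rho of the second CIRc-005 library with GC content was -0.076, which argues against a steady trend with GC content. A rank correlation cannot show a trend that rises and then falls, so GC content was not excluded as a source. The first CIRc-005 library had a rho of 0.165 with length, which argues against a response to the compound. A length-dependent loss of RNA or of fragments in that library is a candidate explanation, and which step it arose in was not tested.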

How the results depend on the processing

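The limma voom fit in the cells and the fit of 9 cell libraries were chosen after seeing the data. RLE factors, library totals and at least 1 CPM were not tried on the number of genes of the interaction. They kept the total number of genes in each of the other comparisons within 1.5 times. Library totals, however, moved the genes lower with CIRc-014 from 249 to 398. The replicate block and limma on log2(FPKM + 1) in the cells, and 1 surrogate variable in the xenograft, kept the totals within 1.5 times too. With the replicate block, CIRc-004 against DMSO gave 248 genes, CIRc-014 549, CIRc-005 0, PF-07104091 1, CIRc-004 and CIRc-014 against CIRc-005 473 and 780, CIRc-014 against CIRc-004 0 and CIRc-004 against PF-07104091 636. The numbers were not taken as pairs in the main fit because the labels do not say that they mark a shared day. Same-numbered cell libraries deviated together in 3 of 10 group pairs at a correlation over 0.1. The correlations of effects on separate libraries were 0.513, 0.0198 and 0.0940 (Pearson) with at least 1 CPM.

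In the order CIRc-004, CIRc-014, CIRc-005 and PF-07104091 against DMSO, CIRc-004 and CIRc-014 against CIRc-005, CIRc-014 against CIRc-004, and CIRc-004 against PF-07104091, where the 10-library fit gave 263, 549, 0, 1, 437, 774, 0 and 628 genes, no filter gave 580, 966, 276, 37, 1704, 1852, 15 and 1128. Only the groups compared gave 3059, 2774, 0, 559, 0, 0, 16 and 3944. Voom with sample weights gave 2428, 2833, 0, 227, 86, 135, 1 and 3341. Without the second CIRc-005 library the counts were 2218, 3130, 5, 450, 1494, 2353, 2 and 3578. DESeq2 moved CIRc-004 to 410, CIRc-005 to 1, PF-07104091 to 10 and CIRc-004 against CIRc-005 to 763. Leaving out 1 library of the compared groups gave 13 to 23, 79 to 109, 0 to 5716, 0 to 0, 24 to 6469, 116 to 6301, 0 to 0 and 38 to 91 genes, where the lone library of a group is assumed to vary like the other groups. The highest 3 came without the first CIRc-005 library, which leaves the second alone in its group. The counts of the 9-library fit rest on a smaller common dispersion. Fits of only the groups compared held no CIRc-005 library unless CIRc-005 was compared, and then held the second one. Voom gave the CIRc-005 libraries weights of 0.200 and 0.215, the first one included, against 1.288 to 1.727 for the other cell libraries. Whether these settings account for the other counts was not tested.

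In the xenograft, 5 genes became 9 with no filter, 33 with DESeq2, 3 on log2(FPKM + 1) and 16 with voom, and 4 or 5 without any 1 tumour. The interaction went from 45 to 227 genes with DESeq2 and to between 2 and 64 without any 1 library. Of the values of named genes under these alternatives, 383 of 476 for CIRc-004 and 527 of 616 for CIRc-014 against DMSO kept their direction and their side of the threshold, as did 118 of 154 for PF-07104091 and 265 of 284 in the xenograft, while 69, 73, 4 and 13 lost the call and 24, 14, 32 and 6 gained it. The sign turned for 3 genes that had not passed in the comparison concerned. CDK1 with CIRc-014 was -0.0113 with library totals and -0.15 to 0.25 without 1 library. E2F1 with CIRc-005 was -0.0448 to 0.329 without 1 library. CCNB1 with CIRc-014 against CIRc-004 was -0.0220 to 0.104 without 1 library, and the cause of these turns was not tested. Of 231 list tests 100 passed at the preset correlation, 15 with an estimated correlation, 75 with fry, 101 with RLE factors and 103 with library totals. With the block, 82 of 184 list tests in the cells passed against 80 without it. At 11651893 to 18387442 counts per library, changes of 1.5-fold were recovered less often than those of 2-fold in each simulated comparison.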

Other observations

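The tests of the host transcript of SEPT14P12, and of the endothelial markers and of the second library for BMP3, and the interval for SEPT14 and its other copies, were chosen after the values were seen. With CIRc-014 against DMSO in the cells, each of the following lists lost its call with an estimated correlation. HSPH1 and HSPA8, heat shock genes encoding chaperones, rose by 0.63 ± 0.10 and 0.51 ± 0.11 (list median 0.30, camera adjusted p = 0.00147, and adjusted p = 0.112 with an estimated correlation). The cholesterol synthesis list had a median of 0.21 (camera adjusted p = 0.0053, and adjusted p = 0.112 with an estimated correlation). Of 26 histone genes 3 fell (6 when adjusted over the list alone), among them HIST1H2AC and HIST1H1C (-1.92 ± 0.37 and -1.04 ± 0.24), with a list median of -1.01 (camera adjusted p = 1.55e-07, and adjusted p = 0.115). MYC, NR4A1 and MAFF fell among 26 immediate early genes (median -0.37, camera adjusted p = 2.38e-05, and adjusted p = 0.112), and TNFRSF10B, ZMAT3, BTG2 and CDKN1A among 29 p53 target genes (median -0.30, camera adjusted p = 0.00482, and adjusted p = 0.112). Without the second CIRc-005 library, 7 of 15 heat shock genes and 9 of 24 cholesterol synthesis genes rose (8 and 11 when adjusted over the list alone), 6 of 29 histone genes and 13 of 28 immediate early genes fell (6 and 15 when adjusted over the list alone), and 13 p53 target genes fell and 4 rose (15 and 4 when adjusted over the list alone).

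With CIRc-014 in the cells, the camera adjusted p was 0.00342 for ATF4 stress response genes (median -0.26), 0.00514 for NF-kB target genes (-0.19), 0.0269 for interferon-stimulated genes (-0.17) and for hypoxia and glycolysis genes (-0.11), 0.0377 for cyclin, CDK, RB and E2F family genes (0.07), 0.0401 for homologous recombination and Fanconi genes (-0.13) and 0.0449 for mitochondrially encoded genes (0.25). With an estimated correlation the adjusted p of these lists was 0.101, 0.112, 0.112, 0.112, 0.142, 0.163 and 0.614. Lists that did not pass were BCL2 family (adjusted p = 0.0604), fibroblast (0.147), neuroendocrine (0.169), ribosome biogenesis and MYC target (0.213), unfolded protein response (0.287, median 0.02 and mean -0.10), ribosomal protein (0.67), endothelial (0.706), keratinocyte (0.939) and tuft cell-like (0.939, median -0.03 and mean 0.02) genes. Markers of macrophages, lymphocytes, muscle and adipocytes and red blood cells had fewer than 3 members measured in the 10-library fit.

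SEPT14P12, a processed pseudogene at chromosome 1 from 197138748 to 197139307 (GRCh38), inside an intron of the mitosis gene ASPM on the same strand, had 0 counts in both DMSO and both PF-07104091 libraries, 4 and 1 with CIRc-005, 136 and 157 with CIRc-004 and 265 and 283 with CIRc-014. Against a floor of 3 counts over the DMSO group it was at least 107-fold higher with CIRc-004 and at least 186-fold with CIRc-014, above the upper 95% bound of 2.87-fold for ASPM, so a higher host transcript level was not the whole source. The median log2 change of 160 other pseudogenes inside same-strand introns was 0.10 (standard error 0.12), which argues against more intronic RNA in general. Single ones ranged from -2.88 (AL021068.2) to 5.23 (PGAM1P6, host ATAD2B at -0.27). None reached SEPT14P12, and a rise limited to some introns was not excluded. SEPT14 and its other copies together had 9 counts in DMSO and 5 with CIRc-014, against 548 of SEPT14P12 (summed CPM ratio 0.565, 95% interval 0.149 to 1.88 from counting noise alone), which argues against reads shared with them. In the xenograft SEPT14P12 had 6 to 33 counts in the vehicle tumours and 26 to 101 in the treated ones, and the 4.26-fold higher level did not pass (edgeR adjusted p = 0.234).

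BMP3, at chromosome 4 from 81030965 to 81057531, had 4669 counts in the first CIRc-005 library, 149 times the DMSO mean in CPM, 479 in the first CIRc-004 library and 25 to 53 in the other 8. The second CIRc-005 library was at 1.37 times the DMSO mean, which argues against a response to the compound. In the first library 6 genes of at least 20 counts, BMP3 among them, lay at 4 times every library of the other groups, including the endothelial markers PECAM1, CDH5 and TIE1 with 174 counts together, and from their 68 counts in the second library 1825 of BMP3 would be expected there against 35 observed (ratio 0.0192), which argues against cells that carry these markers. The median log2 ratio of 3 expressed genes within 1 Mb was -0.0203 (standard error 0.49). RASGEF1B was at 0.35, FGF5 at -0.96 and PRDM8 at -0.02. With 3 genes in 1 library, these values cannot decide on activation of the surrounding region. Activation of the surrounding region stays open. So do cells of another type without these markers and a difference between cultures, neither of which was tested.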
